A study of Homo sapiens with 2 samples.

How the data were processed

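Gene expression was measured in single cells of 2 xenograft tumors of OCI-Ly18, 1 from a mouse given CAR19 T cells with DMSO and 1 from a mouse given CAR19 T cells with venetoclax. Per the labels' protocols, the tumors were minced and dissociated, libraries were made with the Chromium Single Cell 5' kit (chemistry 1.1), and both were sequenced in the same run on a NovaSeq 6000. The authors ran Cell Ranger 5.0.1 against the human GRCh38 reference, and the deposited matrices hold raw UMI counts per gene and barcode, without normalization, for the barcodes that Cell Ranger called as cells. The labels also name Seurat 4.0.1 for later steps, whose output was not used here. No mouse reference is named, so RNA of mouse cells can appear only as far as it matches human genes. Whole-number values and totals that differed between barcodes, from a minimum of 500 UMIs, were checked in both matrices. Symbols and identifiers are those of the files, and coordinates came from GENCODE release 44, which held 36366 of the 36601 identifiers (99.4%).

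Cells were kept with at least 500 UMIs, at least 250 genes and at most 20% of UMIs from mitochondrial genes. Too few genes removed 102 barcodes with DMSO and 141 with venetoclax, and the mitochondrial limit removed 715 and 897. Scrublet (expected rate 0.06, run per library) marked 0 and 1 barcodes, so doublets were in effect not removed. Both libraries were clustered together without integration, on counts per 10000 after log transformation, 2000 variable genes, 30 principal components, 15 neighbors and Leiden resolution 0.5. Immunoglobulin and T cell receptor segments, mitochondrial and ribosomal genes and sex-linked marker genes were kept out of the variable genes. A cluster took a name when at least 3 markers of a list were each seen in at least 10% of its cells and its 10 leading genes did not speak against the name. A cluster also stayed unnamed when its median depth was below 1/3 of its libraries' median and no marker of the list was among its leading genes. This depth condition was not part of the naming rule written beforehand. Clusters 0 (led by HIST1H4C, H2AFX and HIST1H1E), 1 (KDM5B, PTPN6 and NEIL1), 2 (GBP1, GBP4 and IFITM1), 3 (CDC20, SNHG3 and HPDL) and 5 (CCNB1, PLK1 and UBE2C) were named lymphoma-like. Cluster 4 (NEAT1, SPEN, PDE4B, SYNE2 and BCL2) showed 15 of 16 lymphoma B cell markers. By the depth condition, with a median depth of 0.272 of its libraries' median, it stayed unnamed and out of the class comparisons. No cluster was T-like. The marker lists summed over kept cells gave, with DMSO and venetoclax, 11538 and 11092 CPM for lymphoma B cells (most from CD74), 271 and 209 for T cells (most from IL7R and TRBC2), 4.29 and 3.63 for NK cells, 24.1 and 25.3 for myeloid cells (most from CST3), 3.79 and 2.67 for fibroblasts, 1.34 and 0.943 for endothelial cells, 0 and 0 for erythroid cells and 118 and 108 for keratinocytes (most from KRT10).

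UMIs were summed per gene over the lymphoma-like cells of each library, divided by the library's sum and given as CPM with exact Poisson 95% intervals. Ratios are venetoclax over DMSO on the log2 scale, with intervals from the exact binomial share of the UMIs of both libraries, and a count of 0 to 2 was set to 3 for a ratio. The genes named from the whole transcriptome are among the 10 highest and the 10 lowest ratios among 4389 genes with at least 100 UMIs over both libraries and a mean of at least 20 CPM. Mitochondrial, ribosomal, immunoglobulin and T cell receptor segment genes, sex-linked marker genes, 3 HLA-DRB genes that differ in number between people and clone-based names were left out of that choice. BCL2, BCL2L1, MCL1 and BCL2A1 were named in any case, and from each list up to 4 members with the largest absolute ratio could be named. Results of some single genes that these rules select are not reported here, although the genes remain in every sum and list. The 31 gene lists covered the anti-apoptotic and pro-apoptotic BCL2 family, death receptors and caspases, p53 targets, S phase, G2/M phase, interferon gamma response, type I interferon response, MHC class I, MHC class II, B cell receptor and surface, germinal center, plasma cell, NF-kB, hypoxia, glycolysis, oxidative phosphorylation, ATF4 and integrated stress response, endoplasmic reticulum stress, cholesterol synthesis, MYC targets, dissociation and immediate early genes, cytotoxic effectors, T cell cytokines and chemokines, inhibitory receptors and exhaustion, memory and resting T cells, T cell activation, regulatory T cells, CD4 helper lineage, CD8 lineage, and lymphocyte traffic and adhesion. A member was measured with at least 30 UMIs over both libraries, and lists with at least 5 measured members were set against 10000 random lists matched on 10 bins of mean CPM. Shares of lymphoma-like cells with a UMI of a gene were taken after thinning every cell to 1800 UMIs, the 10th percentile of the library where it was lower.

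The groups, cell filters, clustering, marker and gene lists, named-gene rule and most alternatives were chosen before the data were examined. With 1 library per group, cells and genes are not replicates, so no p-value, no error between mice and no number of changed genes is given. The alternatives covered the mitochondrial limit, the UMI minimum, the Scrublet calls, barcodes with UMIs of both classes, the cluster resolution, classes set from marker UMIs, cells without a UMI of 6 cell cycle genes (MKI67, TOP2A, CDK1, TYMS, RRM2 and PCNA), 2 other scalings, equal weight per cell and other count minimums. Including the unnamed cluster, leaving out T cell barcodes, thinning for the sums and the T cell barcode rule were added later. Intervals of differences between cell cycle shares combine the exact intervals of both shares in quadrature. The calculation was tested on simulated data drawn as Poisson counts from the mean expression of both libraries at their sizes, with known changes in 200 of 11871 genes. That expression was summed over all cells that passed the filter, not over lymphoma-like cells alone. There, 95.4% of unchanged genes had 0 inside their interval, and the true change lay inside for 92.5% of genes changed 1.5 times, 92.5% changed 2 times and 97.0% changed 4 times. A list raised 1.5 times had a median of 0.65 above all random lists, and 2% of lists of unchanged genes lay beyond the central 95%. The draws share the Poisson assumption of the intervals and treat genes as independent. They check the calculation only, not how well intervals or percentiles hold where UMIs gather in single cells. Subtraction of free RNA was not run, because no T-like class was found. The CAR construct is not described in the labels and its RNA was not analysed here. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.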

Results

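Single-cell RNA sequencing was done on tumors of OCI-Ly18, a line of human diffuse large B cell lymphoma, that had grown under the skin of NSG mice, which make no T, B or NK cells of their own. Each mouse had been injected with 5000000 OCI-Ly18 cells and then infused with 2500000 human T cells carrying a chimeric antigen receptor (the CAR19 cells of the labels). The mouse of one group received the vehicle DMSO, and the mouse of the other received venetoclax, an oral drug that binds BCL2 and blocks its anti-apoptotic function, at 50 mg/kg per day until the tumors were taken on day 14. The CAR19 with DMSO group and the CAR19 with venetoclax group each held 1 library from 1 mouse, so there was no replicate check on any difference and no test was run. The DMSO library held 8561 barcodes with 60133646 UMIs (unique molecular identifiers, each counted as 1 RNA molecule), and the venetoclax library held 7112 barcodes with 51376143 UMIs. After filtering, 7744 cells of the DMSO library (90.5%) and 6073 cells of the venetoclax library (85.4%) were kept, with medians of 7384.5 and 8304 UMIs per cell. Intervals are at 95%, exact for UMIs (Poisson), ratios and shares (Clopper-Pearson) and from Poisson draws for standard deviations and list medians, and they cover counting error only.

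The first comparison asked how many infused T cells were recovered from each tumor. CD3D, a chain of the T cell receptor complex that only T cells should carry here, had 3 UMIs in the kept cells of the DMSO library and 22 in those of the venetoclax library. CD3E, its partner in the same complex, had 7 and 11 UMIs. Barcodes with 2 or more UMIs of CD3D, CD3E, CD3G and CD2 numbered 1 of 7744 cells in the DMSO library (0.0129%, interval 0.000327% to 0.0719%) and 6 of 6073 in the venetoclax library (0.0988%, interval 0.0363% to 0.215%), a rule chosen after the data were seen. These 1 and 6 barcodes carried most UMIs of GZMB, the granule protease with which cytotoxic lymphocytes kill: 45 of 46 in the DMSO library and 156 of 165 in the venetoclax library. They also held 38 of 39 and 85 of 96 UMIs of GZMA, a related protease, and 57 of 59 and 41 of 41 UMIs of GNLY, which encodes the membrane-lysing granulysin. CD4 had no UMI in either library, and CD8B, a chain of the CD8 coreceptor, had 0 and 3 UMIs. No cluster met the definition of T-like cells in either library, with 0 of 7744 and 0 of 6073 cells in one, which sets no limit on T cells, since the 1 and 6 T cell barcodes lay in lymphoma-like clusters. T-like expression, T-like gene lists and the CD8B share among T cells were therefore not compared. Other genes often used as T cell markers were spread over many kept cells instead. Without thinning, a UMI of TRBC2, a constant segment of the T cell receptor, was seen in 35.9% and 46.4% of all kept cells, and one of IL7R, the interleukin 7 receptor, in 59.0% and 38.4%.

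Lymphoma-like clusters held 7087 cells in the DMSO library (91.5%, interval 90.9% to 92.1%) and 5485 in the venetoclax library (90.3%, interval 89.5% to 91.1%), the T cell barcodes included, and an unnamed cluster of cells with few UMIs held 8.48% (7.87% to 9.13%) and 9.68% (8.95% to 10.5%). That order depended on the processing. Unnamed shares were 6.31% and 3.07% at 10% mitochondrial UMIs, 9.28% and 7.96% at 1000 UMIs and 15.8% and 18.5% without a mitochondrial limit. They were 11.6% and 8.94% without barcodes of both classes and 13.7% and 9.40% at resolution 1.0. The other cells were lymphoma-like each time. Lymphoma-like cells of the DMSO library lay mostly in clusters 0 and 1, and those of the venetoclax library mostly in clusters 2 and 3, with median depths of 7532 and 8571 UMIs per cell. Summed over these cells, the libraries held 55510733 and 47800958 UMIs, and levels are given in CPM, counts scaled to an equal total for both libraries.

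The next comparison set the drug's target and its anti-apoptotic relatives side by side in lymphoma-like cells. BCL2 (ENSG00000171791, chromosome 18, 63123346 to 63320128 in GRCh38) was at 116 CPM (interval 113 to 119) with DMSO and 99.7 CPM (96.9 to 103) with venetoclax, a log2 ratio of -0.22 (-0.27 to -0.16). In the cells without a UMI of 6 cell cycle genes, the BCL2 ratio had the opposite sign at 0.55. BCL2L1, which encodes the anti-apoptotic protein BCL-XL, was lower in the venetoclax library, at 23.6 against 37.3 CPM and a log2 ratio of -0.66 (-0.77 to -0.55), and at -1.35 in the cells without a UMI of those 6 genes. MCL1, another anti-apoptotic relative that venetoclax does not bind, was higher, at 29.5 against 22.4 CPM and a log2 ratio of 0.40 (0.29 to 0.51). BCL2A1, an anti-apoptotic NF-kB target, had 3 UMIs with DMSO and 19 with venetoclax, a log2 ratio of 2.88 with an interval of 1.11 to 5.28, while thinning of cells to 1800 UMIs gave 0.32, the value for counts at or below the floor of 3 in both libraries. The 4 measured anti-apoptotic genes, with BCL2L2 but without BCL2A1, which had fewer than 30 UMIs, had a median log2 ratio of -0.30. Of these, 1 was at least 1.5 times lower in the venetoclax library and none as much higher. With all 6 members of at least 1 UMI, BCL2A1 included, the median changed sign to 0.09.

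Among all lymphoma-like transcripts, interferon-induced genes took most of the highest ratios. IFITM1 (ENSG00000185885, chromosome 11, 310041 to 315272), a membrane protein that restricts virus entry, was at 5.80 CPM (interval 5.18 to 6.47) with DMSO and 90.2 CPM (87.5 to 92.9) with venetoclax, 15.5 times higher (log2 ratio 3.96, interval 3.79 to 4.13). IFI27 (ENSG00000165949, chromosome 14, 94104836 to 94116695), a common marker of interferon exposure, was 9.88 times higher, at 133 against 13.4 CPM. The interferon-inducible GTPases GBP1 (ENSG00000117228, chromosome 1, 89051882 to 89065360) and GBP4, its neighbor on the same chromosome, had log2 ratios of 2.78 (2.67 to 2.89) and 2.63 (2.49 to 2.76). The antiviral GTPase MX1 had a log2 ratio of 2.15, the lysosomal reductase IFI30 1.85, the phospholipase PLAAT4 1.76 and the tryptophanyl-tRNA synthetase WARS, an interferon gamma target, 1.69. SMIM14, a small membrane protein, was also among the highest with 2.18.

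At the other end stood genes of varied function. RPRML (ENSG00000179673, chromosome 17, 46978156 to 46979253), a relative of the cell cycle inhibitor reprimo, was lower in the venetoclax library, at 4.87 against 37.6 CPM (log2 ratio -2.95, interval -3.15 to -2.75). COL9A3, a collagen chain, followed at 9.94 against 39.4 CPM and a log2 ratio of -1.99 (-2.13 to -1.84), and BEST3, of the bestrophin chloride channels, at 19.6 against 70.9 CPM and -1.85 (-1.96 to -1.75). MT1X, a metallothionein that binds zinc and copper, was at 46.3 against 144 CPM (log2 ratio -1.64), and NEIL1, a glycosylase of base excision repair, at 38.5 against 117 CPM (-1.60). F13A1, which encodes the A chain of clotting factor XIII, had a log2 ratio of -1.53, and DOK3, an adaptor that dampens B cell receptor signaling, one of -1.48. RASSF6 (-1.47), the E2F partner TFDP2 (-1.43) and the lipoprotein receptor VLDLR (-1.37) completed the 10 lowest. Over the 4512 genes with at least 100 UMIs and a mean of at least 20 CPM, the standard deviation of the log2 ratio was 0.335 (interval 0.334 to 0.336). Over the 4389 of them from which genes were named, the median was 0.09 and the central 95% ran from -0.66 to 0.58. Scaling to UMIs without mitochondrial, ribosomal, immunoglobulin and T cell receptor genes, which took 41.4% of UMIs with DMSO and 36.9% with venetoclax, moved every log2 ratio by -0.11, and median-of-ratios scaling moved them by 0.07. None of these named genes or the anti-apoptotic BCL2 family genes changed sign between the scalings.

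**Figure D1:**
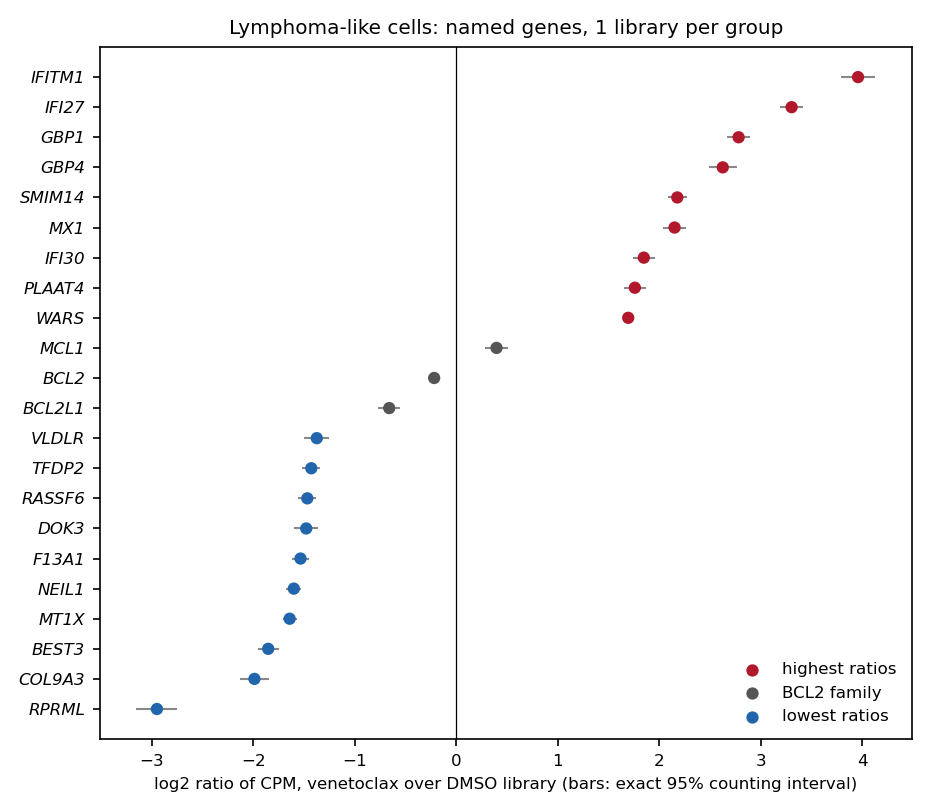
Log2 ratio of CPM, venetoclax over DMSO library, in lymphoma-like cells for genes among the 10 highest and 10 lowest and for BCL2, BCL2L1 and MCL1, with exact 95% counting intervals as bars. IFITM1 lies highest at 3.96 and RPRML lowest at -2.95, while the BCL2 family genes plotted lie between -0.66 and 0.40.

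Gene lists written before the data were examined were then compared as medians of the log2 ratio over their measured members, each set against 10000 random lists of equal size and similar expression. These percentiles are a description of these libraries. The interferon gamma response list had 12 of 16 measured members at least 1.5 times higher in the venetoclax library and none lower, with a median of 1.20 that lay above all random lists. CXCL10, a chemokine that draws T cells, led it with 4 UMIs against 117, 34.0 times higher (counting interval 12.9 to 127), followed by GBP1, GBP4 and IFI30. With venetoclax, 1 barcode held 59 of the CXCL10 UMIs. The type I interferon response list had 24 of 32 members higher and none lower, and its median of 1.05 also lay above all random lists. The MHC class I list, whose products cut, carry and present peptides to CD8 T cells, had a median of 0.40, again above all random lists. Its largest ratios belonged to the peptide transporters TAP1 (1.54) and TAP2 (0.78) and the immunoproteasome subunits PSMB9 (1.18) and PSMB8 (0.78). MHC class II genes, which present to CD4 T cells, had a median of -0.01 at percentile 12.5, positive under median-of-ratios scaling. It had 2 of 14 members at least 1.5 times higher, IFI30 and the peptide-loading modulator HLA-DOB (0.89), and none as much lower, with the master regulator CIITA at -0.43 and HLA-DPB1 at -0.38. Thinning put this list beyond the central 95% of random lists, at -0.13 and percentile 0.81, while cells without a UMI of 6 cell cycle genes gave 0.28.

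The interferon difference was spread over many cells. With every cell thinned to 1800 UMIs, which left out 689 cells with DMSO and 349 with venetoclax, GBP1 was seen in 1.84% (interval 1.53% to 2.20%) and 12.0% (11.1% to 12.9%) of lymphoma-like cells, against 5.08% and 28.2% before thinning. TAP1 was seen in 10.9% (10.1% to 11.7%) and 26.3% (25.1% to 27.5%) of thinned cells, against 31.3% and 58.8% before. The median cell gave 0.111% of its UMIs to the interferon gamma list with DMSO and 0.222% with venetoclax. Its share for the dissociation and immediate early list was 0.278% with DMSO and 0.556% with venetoclax. Neither library held a class of other cells in which the share from free RNA could be measured, so that background is unknown.

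**Figure D2:**
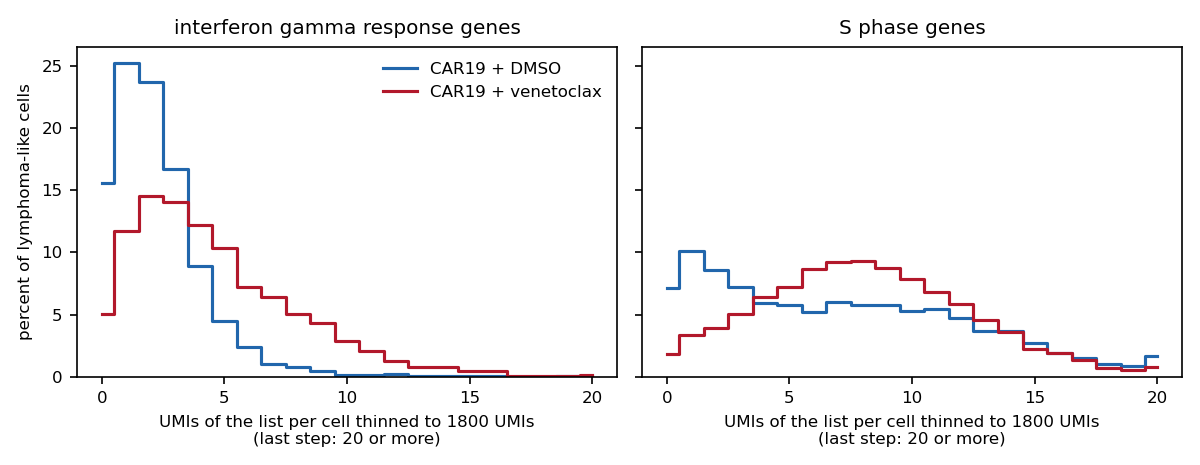
Percent of lymphoma-like cells (vertical axis) by the number of UMIs of the list in the cell (horizontal axis) after thinning to 1800 UMIs, for the lists in the panel titles, with the CAR19 with DMSO library in blue and the CAR19 with venetoclax library in red. For the interferon gamma list the whole distribution lies further right in the venetoclax library, with medians of 0.222% against 0.111% of UMIs.

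Of the B cell identity lists, the one of B cell receptor and surface genes lay beyond the central 95% of random lists. It had a median of -0.19 over 21 members at percentile 0.155, with 1 member at least 1.5 times lower and none as much higher, led by TNFRSF13C, the receptor for the survival factor BAFF (-2.30), while the CD20 gene MS4A1 was higher (0.55) and the signaling enzyme PLCG2 lower (-0.49). The median of this list was -0.09 (interval -0.22 to -0.05) among cells with at most 5% mitochondrial UMIs, -0.11 (-0.37 to 0.07) in cells without a UMI of 6 cell cycle genes and 0.04 (-0.13 to 0.12) in the unnamed cluster. In the germinal center list 3 of 17 members were at least 1.5 times higher and 3 lower, and the median was -0.13 at percentile 3.34, with NEIL1 at -1.60, the migration receptor S1PR2 at -1.09 and the signaling adaptor STAP1 at 1.07. Limits of 10% mitochondrial UMIs or 1000 UMIs per cell, among other alternatives, put that list at percentiles 2.29 and 2.49, beyond the central 95%, while thinning gave -0.07 at percentile 8.76, every member of at least 1 UMI -0.06 at percentile 6.54 and equal weight per cell percentile 5.04. Plasma cell genes had a median of -0.06 at percentile 19.6, which was 0.13 at percentile 43.7 in cells without a UMI of 6 cell cycle genes and marginally positive under median-of-ratios scaling, with the plasma cell regulators IRF4 (-1.89) and PRDM1 (-1.23) lower and the antibody joining chain JCHAIN higher (0.96).

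Of the death gene lists, the one of death receptors and caspases lay beyond the central 95% of random lists. The death receptor and caspase list had a median of 0.22 at percentile 99.9 over 15 members, of which 1 was at least 1.5 times higher and none as much lower. The death receptor FAS was at 1.62, cytochrome c (CYCS) at 0.54 and CASP8 at 0.52, against -0.48 for CFLAR and -0.34 for APAF1. Pro-apoptotic BCL2 relatives, of which 2 of 9 were at least 1.5 times lower and none as much higher, had a median of 0.07 at percentile 57.6, which turned negative with scaling to UMIs without mitochondrial, ribosomal, immunoglobulin and T cell receptor genes. BBC3, which encodes the BH3-only protein PUMA, was at -0.81 and HRK at -0.64, against 0.48 for BID. Targets of the tumor suppressor p53 had a median of 0.08 at percentile 91.3, also negative under that scaling, with TP53INP1 at -2.28. The NF-kB targets had a median of -0.06 at percentile 58.5, positive under 6 of 16 alternatives and at most 0.20. Among them were the chemokines CCL4 at -1.35 and CCL3 at -0.90 and the apoptosis inhibitor BIRC3 at 0.79. CCL22 was at 4.09, but all 44 of its UMIs lay in 1 T cell barcode of the venetoclax library. Without the T cell barcodes the median was -0.10.

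Metabolic lists lay on opposite sides of 0. All 20 cholesterol synthesis genes were measured, 8 were at least 1.5 times lower and none as much higher, and the median of -0.54 lay below all random lists. SREBF2, the transcription factor that drives the pathway, was at -1.08, the early synthase HMGCS1 at -1.04 and LSS, which closes the sterol rings, at -0.78. Hypoxia genes had a median of -0.53 at percentile 0.020, with NDRG1 at -1.03 and PFKFB4 at -0.86, although the surface enzyme CA9 was higher (0.90), and the median was 0.33 in cells without a UMI of 6 cell cycle genes. Glycolysis genes had a median of 0.20 at percentile 86.8, with the lactate exporter SLC16A3 at -1.33 and ALDOC at -1.24. Oxidative phosphorylation genes had a median of 0.29 at percentile 97.8, inside the central 95% of random lists when cells were thinned (94.1), limited to 10% mitochondrial UMIs (97.4) or without a UMI of 6 cell cycle genes (94.6), with SDHB at 0.66 and ATP5MC1 at 0.60. MYC targets had a median of 0.23 at percentile 97.0, or 97.9 with every member of at least 1 UMI, led by the mitochondrial chaperone gene HSPE1 (0.74). In the unnamed cluster the oxidative phosphorylation median was -0.004 (interval -0.05 to 0.06).

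Cell cycle and stress lists were compared in the same way. S phase genes had a median of 0.15 at percentile 90.8 over 41 members, beyond the central 95% of random lists when cells were thinned (0.26, percentile 99.7), and RFC2, a clamp loader subunit, was at 0.62. G2/M genes had a median of 0.06 at percentile 28.6 over 52 members, negative when scaled to UMIs without mitochondrial, ribosomal, immunoglobulin and T cell receptor genes, and CDC20, an activator of the anaphase-promoting complex, was at 0.69. In cells without a UMI of 6 cell cycle genes, the S phase median was 0.55, above all random lists, and the G2/M median 0.46, beyond their central 95%, while in cells with such a UMI they were 0.09 and -0.01. The 6 genes belong to these lists, and cells were chosen by them without thinning. At 1800 UMIs, 22.0% of cells with DMSO and 9.29% with venetoclax lacked such a UMI. The cells so chosen may thus differ in cycle state between the libraries, and these medians draw no conclusion on the cell cycle. A UMI of any of 6 cell cycle genes was seen in 78.0% (76.9% to 79.0%) and 90.7% (89.9% to 91.5%) of thinned cells, against 88.2% and 95.9% before thinning. ATF4 and integrated stress response genes had a median of 0.04 at percentile 48.7 and endoplasmic reticulum stress genes one of 0.06 at percentile 39.3, both negative under that same scaling, with ATF5 at -0.90, the stress-induced DDIT4 gene lower as well and the mannosidase-like EDEM1 at -0.93. In cells without a UMI of 6 cell cycle genes these medians were 0.66 and 0.55, above all random lists. Dissociation and immediate early genes took a larger share of UMIs in the median thinned cell of the venetoclax library, as given above. They had a median of 0.20 at percentile 98.6. It was -0.42 with each cell weighted equally, and inside the central 95% when thinned (percentile 85.5), with classes set from marker UMIs (93.3) or in cells without a UMI of 6 cell cycle genes (27.6), with the heat shock genes HSPA1A at -2.32 and HSPA6 at 1.30.

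T cell lists were read in lymphoma-like cells, where the few T cell barcodes weigh on genes with low counts. Cytotoxic effector genes had a median of 0.92 above all random lists over 10 members, which was 0.35 at percentile 98.9 without the T cell barcodes, led by GZMB (2.06) and CTSW (1.75), whose UMIs lay mostly in those barcodes. T cell cytokine genes had a median of 0.85 above all random lists over 8 members, and 0.39 at percentile 98.7 without those barcodes. That median was -0.09 over members with at least 100 UMIs and -0.19 with classes set from marker UMIs, with TNF at 2.22 and the chemokine XCL1 at 2.49, all of whose UMIs (13 and 63) lay in the T cell barcodes. Inhibitory receptor and exhaustion genes had a median of -0.29 at percentile 26.9, with the nuclear receptor NR4A3 at -2.50 and TOX2 at -2.23. That list lay below the central 95% with thinning (-1.27, percentile 0.020), equal weight per cell (-0.71, percentile 1.11) or members of at least 100 UMIs (-0.57, percentile 1.26), and was at 0.22 with every member of at least 1 UMI. That value is the ratio of members at or below the floor of 3 counts in both libraries, set by the UMI totals alone. Memory and resting T cell genes had a median of -0.26 at percentile 2.37, which was 2.76 without the T cell barcodes and thus inside the central 95%, as under most other alternatives. The median of that list, led by IL7R (-1.06), was 0.15 in cells without a UMI of 6 cell cycle genes. T cell activation genes had a median of -0.22 at percentile 6.27 and regulatory T cell genes one of -0.10 at percentile 61.7, with the transcription factor BATF at 1.83 and the TGF-beta docking receptor LRRC32 at -1.81. The activation median was 0.12 at percentile 73.4 with thinning, and with every member of at least 1 UMI both lists were at the floor value of 0.22. Lymphocyte traffic genes had a median of -0.01 at percentile 66.3, positive under 6 of 16 alternatives, with the integrin ITGB7 at 1.86 and the egress receptor S1PR1 at -0.80. The CD4 helper list had 3 measured members with a median of 0.35, led by the follicle-homing receptor CXCR5 (1.95), and the CD8 list had 4 with a median of 0.14, among them KLRC3 at -1.35. In total, 12 of the 28 lists with at least 5 measured members lay beyond the central 95% of random lists.

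**Figure D3:**
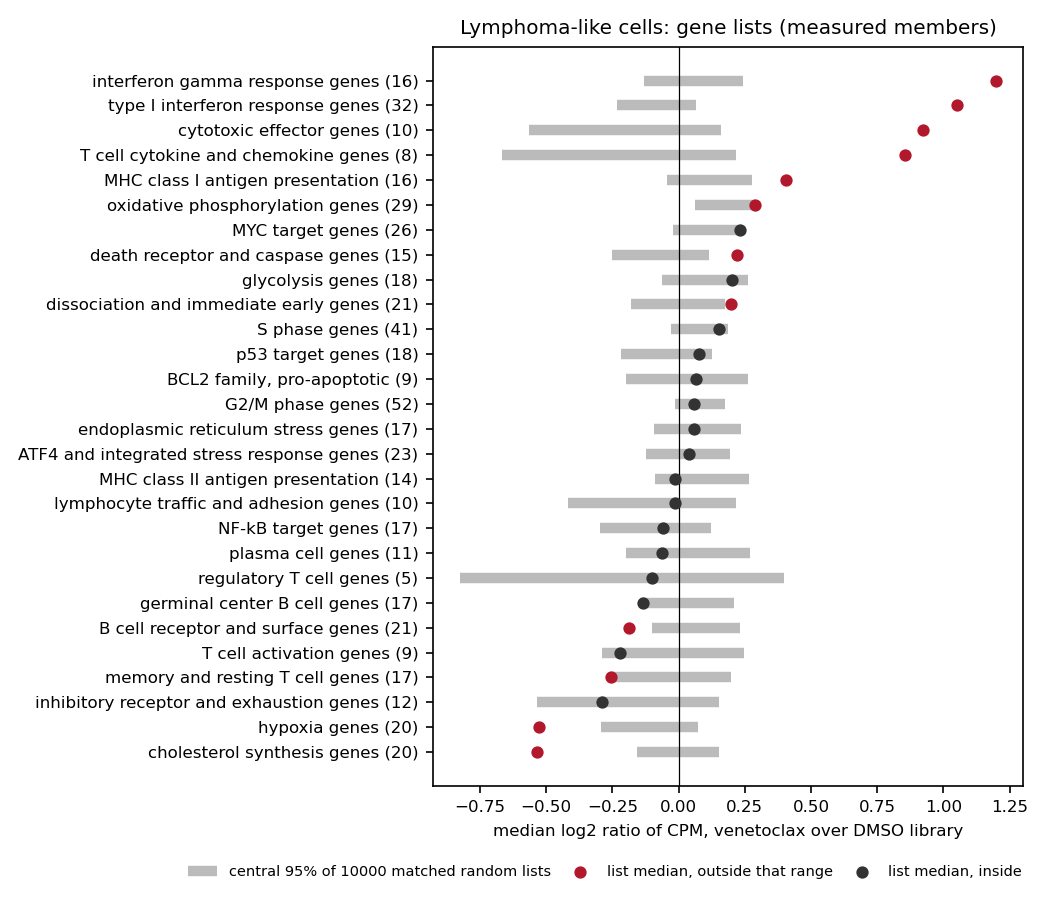
Median log2 ratio of CPM, venetoclax over DMSO library, for each gene list with at least 5 measured members in lymphoma-like cells (points), with the number of measured members in brackets and the central 95% of 10000 random lists as gray bars. The interferon lists lie furthest right at 1.20 and 1.05, and the hypoxia and cholesterol lists furthest left at -0.53 and -0.54, signs that all 3 scalings shared.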

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

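The tests on the interferon genes in this part were chosen only after the result was seen, as was the T cell barcode rule, except that the sum over cells without a UMI of 6 cell cycle genes was chosen before the data were examined, and only its use as a test and its bounds came after. Signals appeared outside the main comparison in 3 places: T cell barcodes, barcodes above the mitochondrial limit and the unnamed cluster. T cell barcodes made up 0.0988% of kept cells in the venetoclax library (6 of 6073, interval 0.0363% to 0.215%), against 0.0129% in the DMSO library (1 of 7744, interval 0.000327% to 0.0719%). In the venetoclax library, 1 barcode held 160 of 161 UMIs of IL3, a cytokine of activated T cells, and 1 barcode held 133 of 134 UMIs of CCL1, a chemokine of activated T cells. All 44 UMIs of CCL22, which attracts CCR4-positive T cells, likewise lay in 1 barcode of that library, while IL3, CCL1 and CCL22 had 0 UMIs with DMSO. Barcodes above the mitochondrial limit made up 12.9% (12.1% to 13.7%) of those with enough genes in the venetoclax library and 8.45% (7.87% to 9.07%) in the DMSO library, and the difference was not tested.

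The interferon gamma list was also higher in the unnamed cluster, which the report's class comparison left out: its median log2 ratio there was 1.44 (1.24 to 1.53), and GBP1 had 35 UMIs with DMSO and 216 with venetoclax. In lymphoma-like cells, a changed share of cells without a UMI of the 6 cell cycle genes is argued against as the cause. The list's median was 1.58 (1.502 to 1.902) over 13 members in the 839 and 227 cells without such a UMI. It was 1.21 (1.19 to 1.25) in cells with one. Cells chosen this way may differ in cycle state between the libraries, so cycle state itself is not decided. RNA within the T cell barcodes is argued against as well, since they held only 0.0131% and 0.0470% of lymphoma-like UMIs. The median without them was 1.20 (1.12 to 1.27, a range that borrows the width of the main median's interval). T cell RNA free in other droplets is not covered by that value. With all cells thinned to 1800 UMIs the median was 1.21, for which no interval was drawn. CPM already scales to the total, so thinning argues only against a larger weight of deep cells. Interferon from more T cells in the venetoclax tumor may be a source, but the shares of T cell barcodes differed by 0.0859 percentage points (-0.0357 to 0.215, from the opposite ends of both intervals), which includes 0, and IFNG had 0 and 1 UMIs, so this cannot be told apart from no such source. Venetoclax itself, other differences between the 2 mice, free RNA and a difference in the handling of the tumors stay open, as each group had 1 mouse. The median thinned cell gave more of its UMIs to dissociation genes with venetoclax (0.556% against 0.278%), but that list was mixed. Of its 21 measured members, 5 were at least 1.5 times higher and 5 as much lower. Its median log2 ratio was -0.42 with each cell weighted equally, and lay at percentile 85.5 with thinning.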

How the results depend on the processing

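The alternatives that included the unnamed cluster, left out T cell barcodes, thinned cells or used the T cell barcode rule were chosen after seeing the data. Both interferon lists, MHC class I, cholesterol synthesis and the genes reported from the 10 highest and 10 lowest ratios kept their direction under every alternative run, and 227 of 266 values of those genes stayed within their counting interval, with 39 outside it and 0 reversed. Of 448 medians of gene lists under alternatives, 333 stayed within their interval, 110 moved and 5 reversed, the last meaning a changed sign of a list beyond the central 95% of random lists. In all, 31 of the 448 medians, from 16 lists, changed sign, 20 of them outside the interval. The number of lists beyond the central 95% of random lists ranged from 9 to 13. Unless a scaling or a count minimum by its own construction moved a value, the cause was not tested. No paired analysis was possible because each group held 1 library.

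The difference in T-like share was 0 points with clusters, 0.102 points with classes set from marker UMIs and 0.0859 points with the T cell barcode rule. The standard deviation of 0.335 became 0.329 at 10% mitochondrial UMIs, 0.333 without a mitochondrial limit or with classes from marker UMIs, 0.330 at 1000 UMIs, 0.329 without barcodes of both classes, 0.326 at resolution 1.0 and 0.329 with the unnamed cluster. It was 0.487 in cells without a UMI of 6 cell cycle genes, 0.347 with scaling to UMIs without mitochondrial, ribosomal, immunoglobulin and T cell receptor genes, 0.381 with equal weight per cell, 0.355 with thinning and 0.543 with at least 30 UMIs in place of 100 and no limit on CPM, which together add genes with few counts.

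In cells without a UMI of the 6 genes, BCL2 reversed to 0.55, hypoxia genes to 0.33 and memory T cell genes to 0.15, while BCL2L1 was at -1.35, S phase genes at 0.55, G2/M genes at 0.46, interferon gamma genes at 1.58 and type I genes at 1.19. Dissociation genes reversed to -0.42 with equal weight per cell. T cell cytokine genes reversed to -0.19 with classes from marker UMIs and -0.091 over members with at least 100 UMIs.

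S phase genes (0.15) were at 0.12 without a mitochondrial limit, at 1000 UMIs and with Scrublet calls kept, 0.13 without barcodes of both classes, 0.10 at resolution 1.0 and 0.11 with the unnamed cluster. BCL2 (-0.22) was at -0.14 at 10% mitochondrial UMIs and without barcodes of both classes, and at -0.13 at resolution 1.0. Median-of-ratios scaling gave 0.22 for S phase, 0.12 for G2/M and -0.15 for BCL2. Scaling without the mitochondrial, ribosomal and receptor genes gave 0.049, -0.047 and -0.32, and 1.09 for interferon gamma genes, which were at 1.17 with members of at least 1 UMI. Equal weight per cell gave 0.25, 0.16 and -0.38, and -0.89 for BCL2L1. Thinning gave 0.26 for S phase, 0.15 for G2/M, -0.53 for BCL2L1, 0.53 for MCL1 and 0.32 for BCL2A1, the value for counts at or below the floor of 3 in both libraries.

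The number of T cells recovered limits the T cell results: with 1 and 6 barcodes and no T-like cluster, T-like expression, lists and the CD8B share have no value, so their alternatives and the subtraction of free RNA were not run.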

Other observations

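In the unnamed cluster, the anti-apoptotic gene MCL1 was higher in the venetoclax library, at 71.7 CPM (60.5 to 84.3) against 38.8 CPM (32.5 to 46.0), a log2 ratio of 0.89, and BCL2L1 was lower, at 26.5 against 38.2 CPM and a log2 ratio of -0.53. BCL2 was slightly higher there, at 397 against 357 CPM and a log2 ratio of 0.15 (0.02 to 0.28), opposite in sign to lymphoma-like cells. HSPA6, a heat shock gene with little expression outside stress, was also higher there, at 68.7 against 31.7 CPM. Its MHC class I list had a median log2 ratio of 0.50 (0.42 to 0.59). The cells of this cluster had median depths of 2387 and 1794 UMIs, with median mitochondrial shares of 9.33% and 12.5%, against 3.51% and 3.37% in lymphoma-like cells. MS4A1, the gene of the antibody target CD20, was seen in 25.8% (24.8% to 26.9%) of thinned lymphoma-like cells with DMSO and 38.3% (36.9% to 39.6%) with venetoclax, against 52.9% and 75.5% before thinning. COL1A1, a collagen chain of fibroblasts, had 59 UMIs with DMSO, of which 58 lay in 1 barcode, and 16 with venetoclax.

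The tests on the cell cycle, hypoxia and cholesterol genes were chosen before their results were seen. The use of cells without a UMI of the 6 cell cycle genes for the cholesterol result was not among them. Fewer lymphoma-like cells lacked a UMI of the 6 cell cycle genes in the venetoclax library: at 1800 UMIs, 90.7% of its cells had one, against 78.0% with DMSO. Among the 5557 of 6398 and 4682 of 5136 thinned cells with at most 5% mitochondrial UMIs, the shares differed by 12.1 percentage points (10.8 to 13.5). Cells above that limit thus did not make the difference alone. Damage in the many cells below the limit is not covered, so damaged cells as a cause stay undecided. Unequal depth is argued against by a difference of 7.08 points (6.17 to 7.99) among cells with at least 5000 UMIs, each thinned to 5000. Single genes did not all share the difference: at 1800 UMIs, MKI67 was seen in 26.1% (25.1% to 27.2%) of cells with DMSO and 28.3% (27.1% to 29.5%) with venetoclax, and TOP2A in 23.6% (22.6% to 24.7%) and 22.0% (20.9% to 23.2%). No biological explanation was tested, and the treatment, free RNA, cell recovery and other differences between the mice stay open, with 1 mouse per group.

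Hypoxia and cholesterol synthesis genes were lower in the venetoclax library, with medians of -0.53 and -0.54. Cells with a UMI of the 6 cell cycle genes gave -0.52 (-0.58 to -0.44) and -0.54 (-0.58 to -0.48). They were 6248 of 7087 lymphoma-like cells with DMSO and 5258 of 5485 with venetoclax. Their medians thus nearly repeat the main ones and cannot decide whether cell cycle composition set the hypoxia result. Cholesterol genes were lower in cells without such a UMI as well (-0.41, percentile 0.03). The interval drawn for that median, -0.97 to -0.45, leaves out the value itself, so it gives the side of 0 but not the size. For cholesterol genes, a changed share of cells without such a UMI is argued against as the cause. Cells with at most 5% mitochondrial UMIs gave -0.48 (-0.55 to -0.40) for hypoxia and -0.52 (-0.55 to -0.43) for cholesterol genes. They were 5794 of 7087 lymphoma-like cells with DMSO and 4818 of 5485 with venetoclax, so these medians also nearly repeat the main ones. Cells above that limit were not needed for either result, but damage in the other cells is not decided. In cells without such a UMI, 839 and 227 in number, the hypoxia median was 0.33 with an interval that includes 0 (-0.14 to 0.49). In the unnamed cluster the medians were -0.34 (-0.51 to -0.11) and -0.29 (-0.47 to -0.15). No biological explanation was tested, tumor size was not analysed here, and with 1 mouse per group the treatment and the mouse both stay open, as does free RNA.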
